A study of Mus musculus with 8 samples.

How the data were processed

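Messenger RNA was measured in 8 tumour samples grown from MC38 cells, a mouse colon adenocarcinoma line that is syngeneic to the C57BL/6J strain and is widely used to study tumours in animals with an intact immune system. 4 samples from control mice were compared with 4 samples from mice given C26 at 10 mg/kg on alternate days for 2 weeks. C26 is known here only by its code. The sources used here do not say what the control mice received, nor in so many words that each sample came from a separate animal, and if samples shared an animal the p-values measure only the spread between these samples.

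Per the labels' protocols, polyadenylated RNA was isolated with oligo(dT) beads, and per the series design text the libraries were made with a strand-marking Illumina TruSeq kit and read from both ends on a NextSeq2000. The deposited unit is a count, and the authors' table holds whole-number raw counts per Ensembl gene for each sample, although its sheet name mentions FPKM. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, HISAT2 2.2.1 and featureCounts 2.0.1 with the mm10 genome build, whereas the series design text names Cutadapt, STAR, Picard and RSEM with the same build. The whole-number values do not settle which route made the table. The gene annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads shared between ribosomal protein genes and their pseudogenes, between the paired globin genes and between neighbouring Gbp genes could therefore have been assigned in either way, and antisense overlaps cannot be separated.

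The table held 56691 gene identifiers, of which 52073 had a symbol in GENCODE M21, and the rest took 0.769% of all counts. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names. Total counts ran from 17075176 to 21517425 per sample, so that a gene at 1 CPM rests on about the same small number of reads in each library, and intervals or limits from counts cover counting error only. A count of 0 over the 4 control libraries allows up to 3 counts, or 0.039 CPM.

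Genes were kept by the default filter of edgeR 4.0.16 (filterByExpr), which left 15755 genes. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test with robust estimation in R 4.3.3, with group as the sole term, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Genes and list members counted as rising, falling or changed are those past the adjusted threshold, and the others may still have moved without passing. Levels are given as CPM on the TMM scale, with the SD over 4 libraries per group, and log2 CPM used a prior count of 2. Before the data were examined, 54 gene lists were fixed, and 52 of them had the 5 or more tested members that were required. Lists of mast cell and of keratinocyte genes had 3 tested members each and were not tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 52 lists. Measures per library and list means were compared by exact two-sided permutation tests, for which 4 against 4 gives 70 arrangements and a smallest p of 0.0286.

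Genes named in the text followed a rule fixed beforehand. It took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and separate groups, leaving out unnamed genes and pseudogene symbols. It added up to 4 members with the smallest p from each list that camera called or that had at least 3 members past the threshold, and always Ptprc, Cd8a, Gzmb, Ifng, Cd274, Tap1, Mki67 and Vegfa. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen.

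The test was checked on simulated counts for this comparison, drawn for 15755 genes with 200 of them changed. It recovered 16.4% of 67 genes changed by 25%, 67.2% of 67 changed 1.5-fold and 81.8% of 66 changed 2-fold, with 7 false calls among 117. Genes were drawn independently, so differences between libraries that move many genes together, such as muscle RNA, were not simulated. The share of false calls therefore need not hold for the real data.

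The settings varied beforehand were RLE factors, total library size, no low-count filter, a filter of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, leaving out each library, and a log2 limit of 1. Settings chosen after seeing the data were offsets for transcript length and GC content (splines with 4 degrees of freedom fitted per library without listed genes), TMM factors computed without ribosomal protein genes, the mean level of the skeletal muscle list as a covariate, and leaving out C26 libraries 2 and 3 together. Transcript length and GC content came from the principal transcript of each gene in GENCODE M21 and were available for 98.3% of tested genes.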

Results

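Gene expression was profiled in tumours formed by MC38 mouse colon adenocarcinoma cells in C57BL/6J mice, in 4 control samples and in 4 samples from mice treated with C26, to find which transcripts differed after 2 weeks at 10 mg/kg. Total counts were 19730000 ± 1980000 per control library and 19510000 ± 1390000 per C26 library (SD, n = 4 each), and did not differ in an exact permutation test (p = 0.8, adjusted p = 0.8 over 6 library measures). The TMM factor was 0.9749 ± 0.00908 in control and 1.026 ± 0.0055 in C26. The 50 highest genes took 13.97 ± 0.329% and 12.54 ± 0.343% of counts. Both measures had the smallest possible p (exact permutation p = 0.0286, adjusted p = 0.0572). The first principal component held 35.5% of the variance and placed all 4 control libraries between -25.5 and -12.7 and all 4 C26 libraries between 10.2 and 37.8. Spearman correlations across genes (which are not independent replicates) were 0.9909 to 0.9949 among control libraries, 0.9883 to 0.9931 among C26 libraries and 0.9814 to 0.9918 between groups. No pair of libraries matched within sampling noise, since the chi-square per degree of freedom was at least 6.15.

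Transcripts for the protein synthesis machinery and the ATF4 stress response were lower in C26 tumours and matrix and fibroblast transcripts were higher, by camera with its preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.541 for cytosolic ribosomal proteins and 0.638 for ATF4 and fibroblast genes). Of 15755 genes tested, 1223 changed in edgeR's quasi-likelihood test, 574 higher and 649 lower in C26. Most changes were small, with a median log2 fold change of 0.41 among the genes that rose and -0.37 among those that fell, and 114 genes changed by 2-fold or more, 92 of them higher. Of all 15755 tested genes, 2530 had all 4 C26 libraries on one side of all 4 control libraries, which chance gives for 2.86% of genes. Scaled by total library size, 1949 genes passed and 78.7% of them were higher, against 46.9% with TMM factors, and with offsets for transcript length and GC content 678 passed and 30.1% were higher. The count fell to 643 without control library 1, 703 without control library 2, 644 without control library 3 and 725 without C26 library 4.

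Genes for cytosolic ribosomal proteins, which form the translating ribosome together with ribosomal RNA, fell almost as a block. Of 35 listed members 34 fell, the median log2 fold change was -0.41, and 35 fell when adjusted over the list alone. Rps2 was the member that did not pass (edgeR adjusted p = 0.0914). Rps14 (chromosome 18, 60747098 to 60778546) went from 2210 ± 105 to 1550 ± 141 CPM (SD, n = 4 per group), a log2 fold change of -0.51 ± 0.0769 (SE, edgeR adjusted p = 0.00224). Rpl10a went from 1410 ± 60.4 to 1040 ± 39.3 CPM (log2 -0.44) and Rps27a, which encodes a ribosomal protein fused to ubiquitin, from 1590 ± 102 to 1140 ± 46 CPM (log2 -0.48). All genes with ribosomal protein symbols together took 11.55 ± 0.252% of counts in control and 9.27 ± 0.517% in C26 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0572). The list was called by camera (adjusted p = 4.34e-27) and by fry (adjusted p = 0.00422), while camera gave an adjusted p = 0.541 with an estimated correlation. With the skeletal muscle level as a covariate, the median was -0.33 and 0 members passed edgeR's threshold (34 at an unadjusted p under 0.05), and the median SE of a member rose from 0.0714 to 0.102.

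Further lists tied to the making of proteins and to mitochondria were also lower. Of 29 genes for the mitochondrial ribosome and mitochondrial protein upkeep 11 fell, and 11 when adjusted over the list alone, with a median log2 fold change of -0.16. They included Mrps18a (52.8 to 42.5 CPM), Mrps30 (108 ± 6.37 to 87.5 ± 4.83 CPM), the mitochondrial protease gene Lonp1 (331 ± 40.3 to 242 ± 28.1 CPM) and the chaperonin gene Hspe1 (467 ± 10.2 to 390 ± 14.3 CPM). This list passed camera (adjusted p = 7.79e-07) and fry (adjusted p = 0.0106), with an adjusted p = 0.541 under an estimated correlation. Its count was 4 without control library 1, 6 without control library 2, 3 without control library 3, 5 without C26 library 2 and 3 without C26 library 4. Nuclear genes of the respiratory chain had 6 of 32 members lower (9 when adjusted over the list alone, median -0.16). Uqcrq of complex III went from 213 ± 6.34 to 150 ± 13.1 CPM (log2 -0.51, edgeR adjusted p = 0.00189), Ndufa2 of complex I from 99.9 ± 11.5 to 71.8 ± 8.04 CPM, and the complex IV genes Cox4i1 and Cox5a fell by 0.36 and 0.29 on the log2 scale. The respiratory chain count was 3 without control library 3 and 11 without C26 library 1, and the adjusted p was 6.11e-06 by camera and 0.638 with an estimated correlation. Genes of ribosome biogenesis and MYC targets had 6 of 26 members lower (11 when adjusted over the list alone, median -0.23, camera adjusted p = 8.66e-06, adjusted p = 0.638 with an estimated correlation). Among them, Nop16 went from 103 ± 7.11 to 78.9 ± 9.72 CPM, and Nme1, Noc4l and Rrp12 fell by 0.35, 0.32 and 0.34 on the log2 scale. In the proteasome list 1 of 27 members fell (1 when adjusted over the list alone), Psmd4, from 257 ± 9.47 to 205 ± 10.2 CPM. The proteasome median was -0.13, camera's adjusted p was 0.000394 and the adjusted p was 0.638 with an estimated correlation. Psma3, Psmb5 and Psmc5 did not pass, with edgeR adjusted p of 0.0532, 0.0711 and 0.0793. Hspe1 was lost without control library 2 or 3 or C26 library 4, and Cox5a without control library 3. Nme1 was lost without control library 1 or 3 or C26 library 4, and Noc4l without control library 1 or 2 or C26 library 4, with edgeR adjusted p up to 0.0642, 0.0709, 0.0731 and 0.0735. Rrp12 passed without C26 library 2 or 3 and was lost without any other library, and the MYC target median was -0.14 without C26 library 4. With the skeletal muscle level as a covariate, 0 members of the mitochondrial ribosome, respiratory chain and proteasome lists passed in edgeR (16, 8 and 5 at an unadjusted p under 0.05), 3 MYC target members fell, and all 4 lists kept their camera calls. The medians in that fit were -0.26 for mitochondrial ribosome, -0.14 for respiratory chain, -0.17 for proteasome and -0.43 for MYC target genes. With offsets for length and GC, 5 mitochondrial ribosome and 2 respiratory chain members fell, and the respiratory chain and proteasome medians were -0.09 and -0.07.

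Genes of the ATF4 response, a program of stress and amino acid metabolism driven by the transcription factor ATF4, were lower in C26 tumours. Of 25 tested members 9 fell and 18 fell when adjusted over the list alone, and all 25 had a log2 fold change below 0, with a median of -0.36. Atf4 itself (chromosome 15, 80255184 to 80257541) went from 765 ± 65.5 to 548 ± 22.3 CPM (log2 -0.48 ± 0.0735 SE, edgeR adjusted p = 0.00224). Ddit3, which encodes the stress transcription factor CHOP, went from 173 ± 22.2 to 102 ± 15.2 CPM (log2 -0.77), Nupr1 from 203 ± 19.1 to 121 ± 22 CPM (log2 -0.74) and the pseudokinase gene Trib3 from 231 ± 33.4 to 150 ± 17.5 CPM (log2 -0.63). The list was called by camera (adjusted p = 5.14e-09) and not with an estimated correlation (adjusted p = 0.638) or by fry (adjusted p = 0.0605). With the skeletal muscle level as a covariate 4 members passed at a median of -0.51.

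Glycolysis and hypoxia genes were lower as well. In the glycolysis list 4 of 20 members fell (when adjusted over the list alone, 10 fell and 1 rose), and the median was -0.27. Slc16a3, a lactate exporter, went from 232 ± 17.1 to 176 ± 9.69 CPM (log2 -0.40, edgeR adjusted p = 0.00567), Aldoa from 948 ± 85.2 to 750 ± 46.5 CPM, Gpi1 from 511 ± 49 to 398 ± 44.7 CPM and Tpi1 from 536 ± 64.1 to 406 ± 53 CPM. In the hypoxia list 3 of 23 members fell (4 when adjusted over the list alone, median -0.27), namely Higd1a (123 ± 17.5 to 81.8 ± 6.36 CPM), Ankrd37 (17 ± 4.48 to 10.2 ± 1.7 CPM) and the adrenomedullin gene Adm (2.47 ± 0.783 to 1.23 ± 0.253 CPM). Ldha, in both lists, did not pass at 930 ± 130 against 702 ± 107 CPM (edgeR adjusted p = 0.0568), nor did Vegfa, the main angiogenic growth factor gene, at 151 ± 20.1 against 136 ± 18.2 CPM (adjusted p = 0.392). Camera's adjusted p was 0.000218 for glycolysis and 0.0017 for hypoxia, and with an estimated correlation the adjusted p was 0.638 and 0.692. Leaving out control library 3 ended the calls for Aldoa, Gpi1, Tpi1, Ankrd37 and Adm. Gpi1 and Tpi1 were also lost without control library 1 or 4 or C26 library 2, and Tpi1 without C26 library 1. Ankrd37 was also lost without control library 1 or 4 or C26 library 1, 2 or 3, and Adm without control library 1 or 4 or C26 library 2, 3 or 4 (edgeR adjusted p up to 0.109 over these losses). With the skeletal muscle level as a covariate neither list was called, at medians of -0.13 and 0.01.

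**Figure D1:**
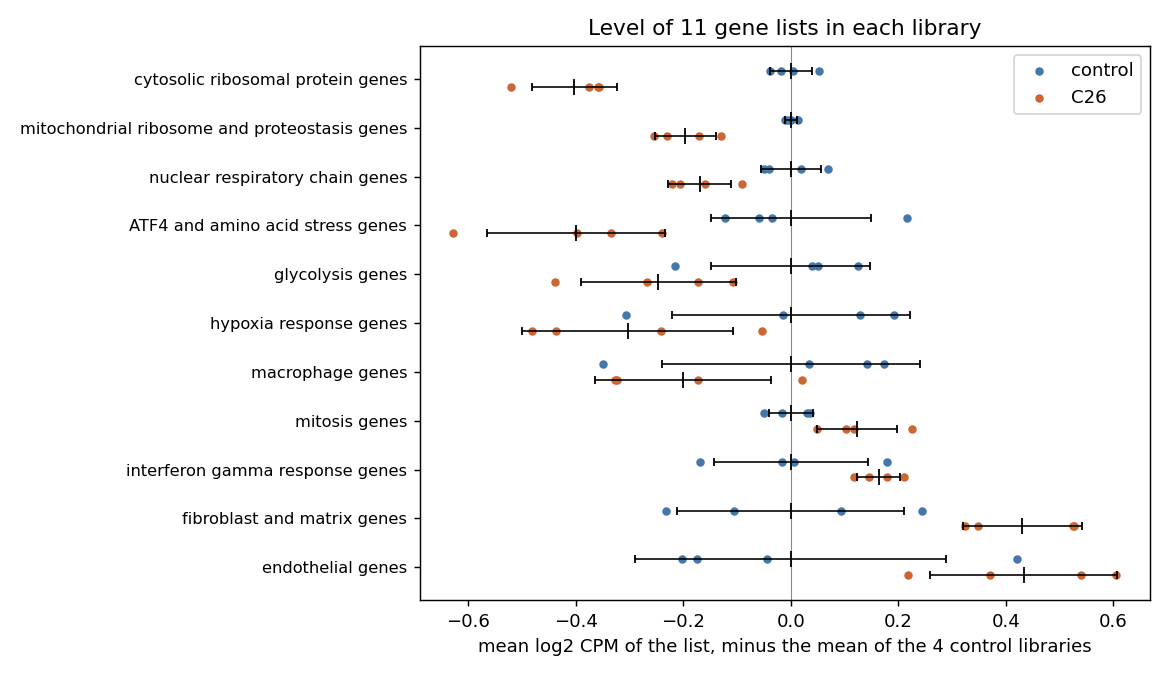
Each point is the mean log2 CPM of a gene list in 1 library, minus the mean of the 4 control libraries, for 4 control (blue) and 4 C26 (orange) libraries, and black marks give the group mean ± SD. The libraries of the groups were separate for cytosolic ribosomal protein, mitochondrial ribosome, respiratory chain, ATF4, mitosis and fibroblast lists and overlapped for the other 5.

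Among markers of the cell types that a tumour sample can hold, fibroblast and matrix genes were higher in C26. Of 24 tested members 8 rose and 13 rose when adjusted over the list alone, with a median log2 fold change of 0.38. Col5a1, a fibrillar collagen gene (chromosome 2, 27886425 to 28039514), went from 420 ± 42.8 to 604 ± 69 CPM (log2 0.52 ± 0.091 SE, edgeR adjusted p = 0.00419). The matrix genes Thbs2 (222 ± 27 to 313 ± 40 CPM), Sparc (1100 ± 78.9 to 1410 ± 111 CPM) and Col6a3 (885 ± 49.4 to 1140 ± 129 CPM) rose as well. Endothelial genes had 3 of 17 members higher (7 when adjusted over the list alone, median 0.43). These were Ptprb (5.04 ± 1.05 to 8.85 ± 0.956 CPM), Mmrn2 (2.38 ± 0.491 to 4.35 ± 1.1 CPM) and the angiopoietin receptor gene Tek (1.55 ± 0.259 to 2.88 ± 0.25 CPM), while the lymphatic marker Lyve1 stood at 1.58 ± 0.463 against 3.11 ± 1.19 CPM (edgeR adjusted p = 0.0503). Camera's adjusted p was 4.06e-07 for fibroblast and 0.00018 for endothelial genes, and with an estimated correlation both had an adjusted p = 0.638. Fry called neither list (adjusted p of 0.0792 and 0.176), and the endothelial levels of the groups overlapped. With the skeletal muscle level as a covariate 6 fibroblast members passed, and 0 endothelial members did in edgeR (6 at an unadjusted p under 0.05). The endothelial count was 1 without control library 1, 7 without control library 3 and 5 without C26 library 4. Tek was lost without control library 1 (edgeR adjusted p = 0.0502), and Mmrn2 without control library 1, 2 or 4 or C26 library 1 (up to 0.0782).

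Skeletal muscle transcripts were very uneven between tumours, with a higher mean in C26 and overlapping groups. The mean log2 CPM of the 15 tested muscle genes was -0.47, 1.75, -0.40 and -0.38 in control libraries 1 to 4 and 2.05, 5.34, 3.45 and 1.28 in C26 libraries 1 to 4 (exact permutation p = 0.0571). Camera called the list (median log2 fold change 3.56, adjusted p = 1.24e-06, and adjusted p = 0.638 with an estimated correlation). All 15 members were above 0, but 1 passed edgeR's threshold, and 1 when adjusted over the list alone, while 10 passed in DESeq2 and 1 in limma-voom. The median was 2.17 without C26 library 2 and 5.09 without control library 2. The member past edgeR's threshold was the fast myosin gene Myh1, at 0.0661 ± 0.132 CPM in control and 3.69 ± 2.31 CPM in C26. Myl1 (0.184 ± 0.336 to 7.69 ± 10 CPM), Mylpf (1.5 ± 0.72 to 17.8 ± 22.3 CPM) and Ryr1 (1.22 ± 0.35 to 5.99 ± 6.14 CPM) did not pass, with edgeR adjusted p of 0.0972, 0.104 and 0.12. Without C26 libraries 2 and 3, the highest in muscle RNA, 897 genes changed, 568 of them shared with the 1223, and 32 ribosomal protein, 15 ATF4 and 10 fibroblast list members passed. In that fit 14 of the 20 list calls were kept and 5 others were gained. With the muscle level as a covariate, 143 genes changed, 88 of them shared. In the covariate fit 0 members of the glycolysis, hypoxia, mitosis, interferon gamma, p53 and unfolded protein response lists passed in edgeR (3, 3, 2, 6, 8 and 3 at an unadjusted p under 0.05). The same fit kept 9 of the 20 list calls. It ended the camera calls for the red blood cell, mitosis, interferon gamma, macrophage, unfolded protein response, NRF2, nucleic acid sensing and lysosome lists. It also ended those for glycolysis, hypoxia and the muscle list itself, the last fixed in advance because that list's mean is the covariate. It gained calls for lower DNA replication (median -0.16, camera adjusted p = 1.78e-05, against 0.02 and 0.97 without the covariate) and DNA damage repair genes (-0.12, 0.00865, against 0.05 and 0.71), with 0 members past edgeR's threshold in either (5 and 3 at an unadjusted p under 0.05). The muscle level shared 56.4% of its variance with the group.

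Red blood cell genes were lower, with a median log2 fold change of -2.12 over 6 tested members (camera adjusted p = 0.000998, adjusted p = 0.638 with an estimated correlation). Of these 1 fell, the beta-globin gene Hbb-bt (1.28 ± 0.837 to 0.248 ± 0.139 CPM, edgeR adjusted p = 0.0136), and 4 fell when adjusted over the list alone. Its near-identical copy Hbb-bs and the alpha-globin pair Hba-a1 and Hba-a2 did not pass, with edgeR adjusted p of 0.0886, 0.082 and 0.082. Without control library 3 the list median was -1.33 and all 3 passed, and Hba-a2 also passed without control library 4. Macrophage genes had a median of -0.18 (camera adjusted p = 0.0279, adjusted p = 0.699 with an estimated correlation), and 1 of 20 members fell (when adjusted over the list alone, 6 fell and 1 rose). This was Arg1, which encodes arginase 1, at 21.3 ± 2.52 in control and 13.7 ± 2 CPM in C26 (log2 -0.63, edgeR adjusted p = 0.00687). C1qa (238 ± 46.6 against 156 ± 31.7 CPM) and Mertk (60.5 ± 2.6 against 72.5 ± 7.2 CPM) did not pass, with edgeR adjusted p of 0.0685 and 0.0549. The macrophage call ended without control library 1 or 3 or C26 library 2 or 4, with camera adjusted p up to 0.118, and with length and GC offsets (0.0597). The macrophage median was -0.29 without control library 4 and also moved by over 1.5 times without C26 library 1.

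Genes induced by interferon gamma were slightly higher, at a median of 0.18 with 5 of 25 members higher, also when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.659 with an estimated correlation). They included the guanylate-binding protein genes Gbp4 (9.41 ± 0.912 to 13.8 ± 1.81 CPM), Gbp5 (16.2 ± 2.2 to 21.9 ± 2.19 CPM) and Gbp7 (42.4 ± 7.14 to 54.1 ± 1.94 CPM) and the chemokine gene Cxcl9 (7.23 ± 1.94 to 12.3 ± 3.23 CPM), and Tgtp2 (log2 0.39), named after its value was seen. The count was 1 without control libraries 1, 3 or 4, 2 without C26 libraries 1, 2 or 3, and 3 without C26 library 4, and the camera call ended without control library 4 (median 0.09, adjusted p = 0.0665). Gbp5 was lost without control library 1, 3 or 4 or C26 library 1, Cxcl9 without control library 1, 3 or 4 or C26 library 1, 2 or 3, and Gbp7 without any library except control library 2, with edgeR adjusted p up to 0.0883, 0.126 and 0.106. With length and GC offsets 0 interferon gamma members passed in edgeR (5 at an unadjusted p under 0.05), while the list kept its camera call. In the list for sensing of nucleic acids 1 of 19 members rose (3 when adjusted over the list alone, median 0.15), the DNA sensor gene Cgas, from 32.3 ± 3.06 to 41.6 ± 5.44 CPM. Cgas was lost without control library 1, 3 or 4 or C26 library 2 or 3 (edgeR adjusted p up to 0.11). Ddx58, Tlr3 and Adar had edgeR adjusted p of 0.0592, 0.0676 and 0.0863. MHC class II genes had a median of -0.26 with 0 of 13 members past edgeR's threshold, 2 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. Cd83, H2-DMa, H2-DMb2 and H2-DMb1 had edgeR adjusted p of 0.08, 0.179, 0.201 and 0.253. Camera's adjusted p was 0.0355 for nucleic acid sensing and 0.0289 for MHC class II, and 0.638 for both with an estimated correlation. The nucleic acid sensing call ended without control library 1 or 4 or C26 library 1 or 3, and the MHC class II call ended without control library 1 or 3 or C26 library 1 or 4, with camera adjusted p up to 0.132 and 0.0948. The nucleic acid sensing median was 0.07 without control library 4 and also moved by over 1.5 times without C26 library 1, and the MHC class II median was -0.15 without control library 3. With length and GC offsets the MHC class II call ended (camera adjusted p = 0.129).

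Of the immune genes that the naming rule always took, none that could be tested passed the threshold in the main fit. Ptprc, the pan-leukocyte marker CD45, was at 41.5 ± 6.6 CPM in control and 40.8 ± 5.08 CPM in C26 (edgeR adjusted p = 0.91). Gzmb was at 6.66 ± 1.89 and 7.71 ± 1.99 CPM (adjusted p = 0.573), Cd274, which encodes PD-L1, at 14.2 ± 1.12 and 14.6 ± 2.04 CPM (adjusted p = 0.862), and Tap1, a peptide transporter gene of antigen presentation, at 141 ± 9.69 and 122 ± 5.04 CPM (edgeR adjusted p = 0.0699). Tap1 passed in 3 of 20 alternative fits. Cd8a and Ifng were too low to test. Cd8a had 20 counts over the control libraries and 4 over the C26 libraries, and Ifng had 0 and 6, all 6 of them in C26 libraries 2 and 3.

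Mitosis genes were slightly higher, at a median of 0.12 with 4 of 27 members higher and 1 lower (when adjusted over the list alone, 6 higher and 1 lower; camera adjusted p = 0.00213, and adjusted p = 0.638 with an estimated correlation). Kif20a, a kinesin gene of cytokinesis, went from 34.5 ± 3.38 to 50.4 ± 8.06 CPM (log2 0.55, edgeR adjusted p = 0.00851), Kif23 from 62.4 ± 2.44 to 76.5 ± 4.49 CPM and Prc1 from 64.2 ± 7.3 to 87.4 ± 15.7 CPM, and Bub1b rose by 0.31 on the log2 scale. The member that fell, named after its value was seen, was the survivin gene Birc5 (log2 -0.28). The proliferation marker Mki67 did not pass, at 469 ± 8.51 against 497 ± 45.4 CPM (edgeR adjusted p = 0.513). The number of risen mitosis genes was 2 without control library 1 or 3, where Kif23 and Prc1 were lost (edgeR adjusted p up to 0.0725 and 0.113). Prc1 was also lost without control library 2 or C26 library 2, 3 or 4. With length and GC offsets the mitosis median was 0.05 and 2 members rose, and with the skeletal muscle level as a covariate it was 0.01 (camera adjusted p = 0.75). In the unfolded protein response list 2 of 20 members rose (when adjusted over the list alone, 4 rose and 1 fell, median 0.12), Dnajc3 (72.6 ± 5.34 to 91 ± 4.93 CPM) and Pdia4 (284 ± 31.7 to 348 ± 30.1 CPM), while Hyou1 and Calr had edgeR adjusted p of 0.0519 and 0.0719. In the NRF2 list 1 of 20 members fell and 0 when adjusted over the list alone (median -0.11), the transketolase gene Tkt (299 ± 1.29 to 255 ± 16.6 CPM). Taldo1, Pgd and Ftl1 had edgeR adjusted p of 0.0693, 0.113 and 0.116. Lysosome genes had a median of -0.10 with 0 of 25 members past edgeR's threshold, 4 at an unadjusted p under 0.05, 0 in DESeq2 and 1 in limma-voom. Sqstm1, Ctsz, Lamp2 and Hexa had edgeR adjusted p of 0.084, 0.0848, 0.0968 and 0.176. Camera's adjusted p was 0.0279, 0.0325 and 0.0427 for the unfolded protein response, NRF2 and lysosome lists, and with an estimated correlation the adjusted p was 0.638, 0.638 and 0.736. The unfolded protein response call ended without control library 1 or 4 or C26 library 1 or 4. The NRF2 call ended without control library 4 or C26 library 1 or 2, and the lysosome call without control library 1 or 3 or C26 library 2 or 3, with camera adjusted p up to 0.123, 0.203 and 0.224. The NRF2 median was -0.06 without control library 4 and -0.17 without C26 library 3, and the lysosome median was -0.04 without C26 library 2. Dnajc3 was lost without control library 1, Pdia4 without any library except control library 2, and Tkt without any library except C26 library 1, with edgeR adjusted p up to 0.0526, 0.137 and 0.125. With length and GC offsets the NRF2 and lysosome calls ended (camera adjusted p of 0.177 and 0.0519).

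**Figure D2:**
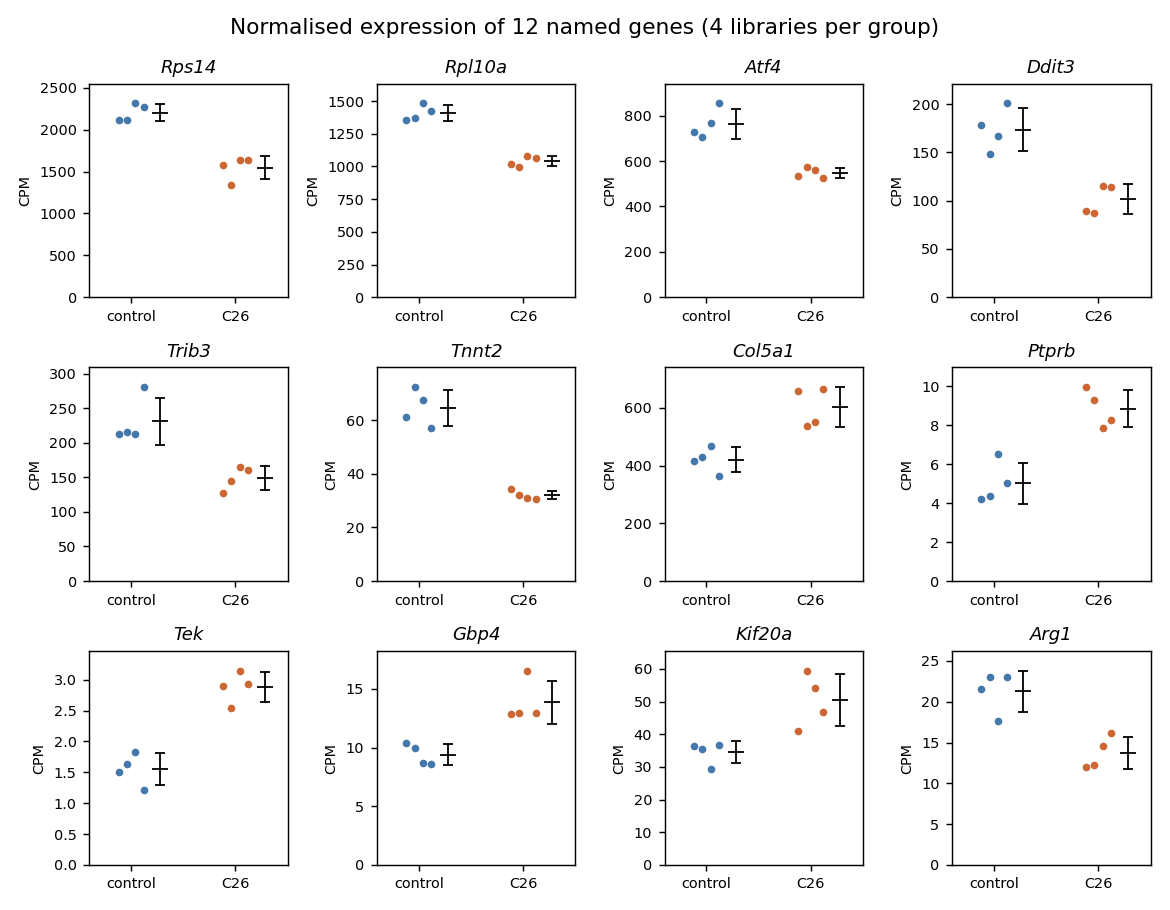
Normalised expression (CPM, linear axis from 0) of 12 named genes in 4 control (blue) and 4 C26 (orange) libraries, with group mean ± SD beside the points. Every gene shown had all 4 C26 libraries on one side of all 4 control libraries, as in Tnnt2 (57 or more CPM in control, 34.3 or less in C26).

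The 10 genes with the largest rises under the naming rule (past the threshold, at least 1 CPM, separate groups) included 6 of striated muscle. Xirp2, Pdlim3, Hspb7, Fhl1 and Nrap, which encode proteins of the muscle sarcomere or its attachments, rose together with Myh1, and each was highest in C26 library 2, the library with the most muscle RNA. Xirp2 had 3 counts in the control libraries and 505 in the C26 libraries, a ratio of 162 (95% interval of counting 55.1 to 788). Pdlim3 went from 0.168 ± 0.135 to 3.1 ± 2.62 CPM (log2 4.15, edgeR adjusted p = 0.0203), Hspb7 from 0.155 ± 0.149 to 2.31 ± 1.94 CPM, Fhl1 from 0.333 ± 0.191 to 3.2 ± 2.13 CPM and Nrap from 0.524 ± 0.227 to 2.35 ± 1.55 CPM. The other 4 encode secreted proteins, namely Thbs4 (0.95 ± 0.413 to 6.39 ± 3.99 CPM), Igfbp5 (1.62 ± 0.774 to 7.57 ± 3.9 CPM), Sned1 (0.37 ± 0.171 to 1.68 ± 0.754 CPM) and C1qtnf3 (1.18 ± 0.703 to 4.64 ± 1.55 CPM), and of these Thbs4 and Igfbp5 were also highest in C26 library 2. Of these 10 genes, Xirp2, Myh1 and Sned1 passed with the muscle level as a covariate in edgeR, and Myh1 is itself in the list that forms this covariate. Xirp2 and Pdlim3 were lost without any 1 of the control libraries, Hspb7 without control library 1 or 3, and Thbs4 without control library 1, 3 or 4. Igfbp5 was lost without control library 3 or 4, Nrap without control library 1, 2 or 3 and C1qtnf3 without control library 3, with edgeR adjusted p up to 0.0923.

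The largest falls under the naming rule (past the threshold, at least 1 CPM, separate groups) were 2.52-fold or less. Tnnt2, the cardiac troponin T gene (chromosome 1, 135836354 to 135852260), had the smallest p of all genes, and went from 64.5 ± 6.81 to 32 ± 1.62 CPM (log2 -1.01 ± 0.0842 SE, edgeR adjusted p = 2.8e-05), opposite in direction to the muscle list. It passed in every alternative fit, with edgeR, DESeq2 or limma adjusted p from 3.68e-26 to 0.00083. Angptl6 went from 14.9 ± 4.91 to 5.88 ± 1.06 CPM (log2 -1.33, edgeR adjusted p = 0.00365), Adm2, a peptide hormone gene of the adrenomedullin family, from 2.71 ± 0.424 to 1.07 ± 0.423 CPM, Myl7 from 3.2 ± 0.445 to 1.26 ± 0.654 CPM and Gdap1l1 from 2.25 ± 0.553 to 0.972 ± 0.162 CPM. Pkp3 went from 3.34 ± 0.204 to 1.66 ± 0.386 CPM, and Cox6c2, Kcnj14, Rapsn and Hes7 fell by 0.92, 0.92, 0.87 and 0.85 on the log2 scale. Kcnj14 did not pass in any of the 8 fits that left out a library. Cox6c2 was lost without control library 2 or 3 or C26 library 2, 3 or 4, Rapsn without control library 1 or 2 or C26 library 3, and Hes7 without control library 2 or C26 library 2 or 3, with edgeR adjusted p up to 0.136. Cox6c2 is annotated as a processed pseudogene, and its reads could be shared with its parent gene.

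The other 32 lists were not called by camera, and 4 of them had at least 3 members past the threshold. Among p53 targets 4 of 23 members fell (when adjusted over the list alone, 5 fell and 3 rose), the apoptosis genes Bbc3 (9.63 ± 0.663 to 6.39 ± 1.21 CPM) and Bax (79.7 ± 2.49 to 65.1 ± 5.94 CPM), Gadd45a (81.3 ± 25.1 to 47.4 ± 4.05 CPM) and Sesn2 (59 ± 9.58 to 43.4 ± 4.85 CPM), the last also an ATF4 list member. All 4 were lost without control library 1, C26 library 2 or C26 library 4 (edgeR adjusted p up to 0.121). Bbc3 was also lost without control library 4, and Bax without any library except C26 library 1. Sesn2 was also lost without control library 2 or 4 or C26 library 1, and Gadd45a without control library 2 or C26 library 1 or 3. Of 19 ERK response genes, Etv4 (102 ± 7.11 to 76.9 ± 10.2 CPM) and Dusp5 (9.17 ± 1.71 to 5.48 ± 1.1 CPM) fell and the pathway inhibitor gene Spred1 rose (89 ± 2.02 to 106 ± 4.35 CPM), with 3 lower and 2 higher when adjusted over the list alone. Areg did not pass (edgeR adjusted p = 0.0551). Among 19 chemokine genes Cxcl16 (53.3 ± 8.74 to 37.3 ± 2.78 CPM) and Ccl5 (53.6 ± 4.83 to 41.9 ± 4.45 CPM) fell and Cxcl9 rose, with the same counts when adjusted over the list alone, and Cxcl2 did not pass (edgeR adjusted p = 0.253). Among 19 angiogenic factor genes Pdgfa fell (61.8 ± 3.86 to 46.9 ± 2.25 CPM) and Vegfd (17 ± 1.85 to 21.9 ± 1.26 CPM) and Pdgfc (35.5 ± 4.2 to 45.6 ± 6.31 CPM) rose, with 1 lower and 3 higher when adjusted over the list alone, and Angpt1 did not pass (edgeR adjusted p = 0.0653). Spred1 was lost without any 1 of the control libraries and without C26 library 4. Ccl5 was lost without control library 2 or 3 or C26 library 2 or 4, and Cxcl9 without any library except control library 2 or C26 library 4. Vegfd was lost without any library except control library 4 or C26 library 2, and Pdgfc without control library 1, 2 or 3 or C26 library 2 or 4, with edgeR adjusted p up to 0.138. Camera's adjusted p for these 4 lists, in the order p53, ERK, chemokine and angiogenic, was 0.565, 0.155, 0.611 and 0.931.

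Of the remaining 28 lists, 15 had 1 or 2 members past the threshold. These members were named after their values were seen, and those outside the naming rule were not followed through the other fits. Zeb2 and Tgfbr2 of the TGF-beta list rose, and Gadd45a and Birc5 of the YAP target list fell. Ncoa4 rose and Gpx4 fell in the ferroptosis list, Xiap rose and Bax fell in the apoptosis list, Dnaja1 rose and Hspe1 fell in the heat shock list, and Ly6a rose and Sox9 fell in the colon tumour cell list. Cyp1b1 of the xenobiotic metabolism list rose (log2 1.36, edgeR adjusted p = 0.0101). Single members fell in the MHC class I (H2-Q7), T cell checkpoint (Vsir), immediate early (Ier2), mitochondrial DNA (mt-Co3), cytotoxic T and NK cell (Ccl5), adipocyte (Pnpla2), nerve and Schwann cell (Ncam1) and cancer stem cell (Sox9) lists. Among the lists that were not called, the median and the camera direction differed in sign for the chemokine and TGF-beta lists (medians 0.03 and -0.01). The other 13 lists, for type I interferon response, NF-kB, complement, cholesterol synthesis, fatty acid synthesis and oxidation, Wnt targets, DNA replication and repair, and neutrophils, dendritic cells, CD4 T cells and B cells, had 0 of 220 tested genes past edgeR's threshold, 34 at an unadjusted p under 0.05, 10 in DESeq2 and 4 in limma-voom. Of these, camera called type I interferon genes higher without control library 2 (adjusted p = 0.000472) and with 1 surrogate variable (0.0472), and DNA replication and repair genes lower with the muscle covariate. Without C26 libraries 2 and 3 it called DNA replication, neutrophil, cholesterol synthesis and NF-kB genes lower (adjusted p of 0.00832, 0.0108, 0.0154 and 0.0498).

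**Figure D3:**
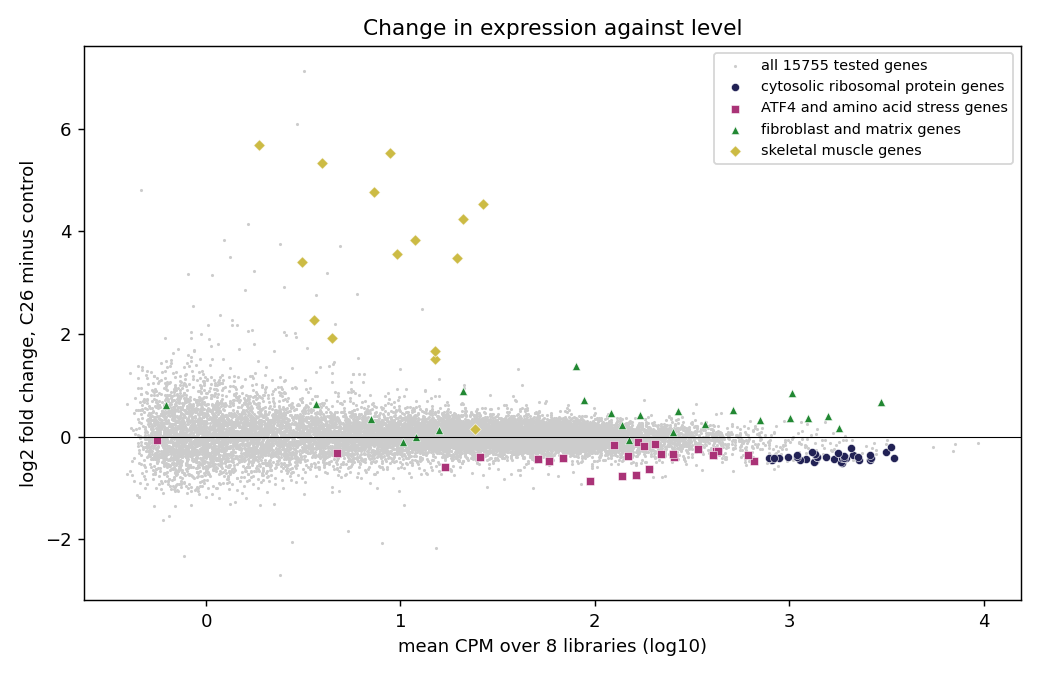
Log2 fold change (C26 minus control) against the mean level over 8 libraries (log10 of CPM) for 15755 tested genes (grey), with members of 4 lists in colour. Ribosomal protein genes lie together below 0 at the highest levels, and skeletal muscle genes spread widely above 0 at low levels.

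Across all 52 lists camera called 20, 7 higher and 13 lower, none of them with an estimated correlation (0 lists, 2 at an unadjusted p under 0.05), and fry called 2. Fold changes followed transcript length and GC content, with a median log2 fold change of -0.13 among unlisted genes with transcripts up to 1310 bases and 0.13 among those with 4450 bases or more. With offsets for both, 27 ribosomal protein, 7 ATF4, 5 fibroblast and 3 endothelial list members passed in edgeR. In the same fit 0 members of the p53, unfolded protein response and nucleic acid sensing lists passed in edgeR (8, 7 and 3 at an unadjusted p under 0.05), and the calls for macrophage, MHC class II, NRF2 and lysosome genes ended. MHC class I, T cell checkpoint, ERK response, ferroptosis, immediate early and mitochondrial DNA lists, not among the 20, were called in some of the other fits, with medians below 0.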

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

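The values of 24 groups of 4 libraries, out of 290 groups tested, held 1 library far from the other 3, where chance alone would give 14.5. The tests for pseudogenes, for the share of tumour cells and for attached muscle as a source of the ribosomal protein and ATF4 falls, and the fits with length and GC offsets or the muscle covariate, were chosen after the main results were seen.

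C26 library 2 had the lowest ribosomal protein level, a mean log2 CPM of 10.3 against 10.5 in the other C26 libraries. Control library 2 had the highest skeletal muscle level of its group, 1.75 against -0.47 to -0.38. It also had more Myh1 (0.264 CPM, 0 in the others) and Myl1 (0.687 CPM against 0 to 0.0494), less Ldha (737 against 979 to 1020 CPM) and more Gbp7 (53 against 37.4 to 40 CPM). In C26 library 2, Mylpf (51 against 3.14 to 9.94 CPM), Ryr1 (15.1 against 1.92 to 4.06 CPM) and Kif23 (83.2 against 73.8 to 74.9 CPM) were high, and C1qtnf3 (2.34 against 5.2 to 5.65 CPM) and Ndufa2 (59.8 against 75 to 76.9 CPM) were low. Control library 3 was high in the globin genes Hba-a1 (29 against 7.22 to 8.37 CPM) and Hbb-bs (57.2 against 11.9 to 16.2 CPM) and low in Kif20a (29.5 against 35.5 to 36.6 CPM). Control library 4 was high in Angptl6 (22.2 against 11.4 to 13.2 CPM), Trib3 (281 against 213 to 216 CPM) and Etv4 (113 against 97.8 to 99.2 CPM). C26 library 1 was high in Gbp5 (25.1 against 20.5 to 21 CPM) and Vegfd (23.8 against 21.1 to 21.6 CPM). C26 library 3 was high in Gbp4 (16.6 against 12.9 to 13 CPM) and Pgd (214 against 189 to 193 CPM) and low in Gdap1l1 (0.73 against 1.04 to 1.06 CPM). C26 library 4 was high in Dnajc3 (98.4 against 87.9 to 89.4 CPM) and low in Hspe1 (369 against 394 to 399 CPM).

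The count of changed genes was compared over all ways to split the 8 libraries into 4 against 4. The real grouping gave 1223 genes in edgeR. Of the 35 ways to split the libraries 1 gave as many, and the highest of the other splits gave 4. With 35 splits the smallest p of such a permutation test is 0.0286, so this rank cannot exclude chance. Every other split mixed control and C26 libraries, so a difference between the groups would widen the spread within each side and lower its count. The gap between 1223 and 4 therefore does not measure how unlikely chance is.

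The fall of ribosomal protein genes (median log2 fold change -0.41) was weighed against 4 technical sources. Offsets for length and GC left a median of -0.30 (-0.33 to -0.28 when each library was left out), and of 3 scalings the one nearest 0 left -0.34 (-0.44 to -0.30). Reads moved to pseudogenes would have raised these, yet ribosomal protein pseudogenes had a median of -0.45 (-0.49 to -0.41). With the muscle covariate the median was -0.33 (-0.37 to -0.27) with a median SE of 0.102 against 0.0714, 0 of 35 members passed edgeR's adjusted threshold (34 at an unadjusted p under 0.05), what ended these calls was not separated, and without C26 libraries 2 and 3 the number was 32. None of the 4, each tried alone, accounts for the whole fall, and they were not tried together. A different mix of cells in the samples was not weighed for this fall. That mix or a response to C26 may underlie it, and both remain hypotheses that these data did not test further.

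The rise of fibroblast and endothelial genes (median 0.42) was weighed against 3 sources. If a lower share of tumour cells raised all other cell types alike, macrophage genes would rise with fibroblast genes. The fibroblast mean minus the macrophage mean went from 0.825 ± 0.13 to 1.46 ± 0.17 log2 units, a difference of 0.632 (exact permutation p = 0.0286, n = 4 per group). The direction of both lists was known when this test was chosen, so its p is not separate evidence. The macrophage median was -0.18, and its camera call ended in 4 of the 8 fits that left out a library. These values argue against an equal rise of all other cell types. They cannot exclude a lower share of tumour cells if fibroblasts took their place more than macrophages did. The 7 tested epithelial and colon tumour cell genes had a median of -0.22, with 5 below 0 and 2 above. That list was not called (camera adjusted p = 0.315), so it does not decide the question. Length and GC offsets left a median of 0.36 (0.28 to 0.44). With the muscle covariate it was 0.57 (0.45 to 0.68), and 6 fibroblast and 0 endothelial members passed in edgeR (6 endothelial at an unadjusted p under 0.05). The muscle level shared 56.4% of its variance with the group, and the median SE of these genes rose from 0.181 to 0.268. This fit therefore cannot exclude tissue attached with muscle. More stroma, or more matrix expression per cell, may underlie the rise. Bulk RNA does not separate these from one another or from tissue taken along at dissection, muscle included.

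The fall of ATF4 response genes (median -0.36) was weighed against 3 sources. Length and GC offsets left a median of -0.37 (-0.44 to -0.31), and the level of hypoxia genes as a covariate left -0.31 (-0.39 to -0.25). With the muscle covariate the median was -0.51 (-0.59 to -0.40), 4 members passed, and the median SE rose from 0.111 to 0.161. A different mix of cells in the samples was not weighed for this fall. That mix, or a response to C26 in tumour or in other cells, may underlie the fall, and both stay untested hypotheses.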

How the results depend on the processing

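The tests with length and GC offsets, with TMM factors without ribosomal protein genes, with the muscle covariate and without C26 libraries 2 and 3 were chosen after seeing the data. The cause of a change was not tested unless stated. The 1223 changed genes (574 higher, 649 lower) became 1949 (1534 higher, 415 lower) with total library size, which moved the median of all genes to 0.0785 and turned Ptprc to 0.0463. They became 1948 (1012 higher) with no low-count filter, 993 were lower in DESeq2, and 2090 (996 higher, 1094 lower) passed with 1 surrogate variable. ATF4 members past the threshold numbered 17, 17 and 18 in these last 3 fits. With length and GC offsets 678 genes passed (204 higher), with 5 fibroblast members, and Cd274 (-0.0548) and Mki67 (-0.10) turned. With a log2 limit of 1, 114 genes passed (92 higher, 22 lower), since the limit removes smaller changes. Without C26 libraries 2 and 3, ATF4 members past the threshold numbered 15.

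With the muscle covariate 143 genes (96 higher, 47 lower), 11 lists (9 of the 20, and 2 gained) and 2 cell type lists passed, with 0 ribosomal protein members in edgeR (34 at an unadjusted p under 0.05), 4 ATF4 members and 0 endothelial, mitochondrial ribosome and respiratory chain members (6, 16 and 8 unadjusted). The medians of the muscle (-0.18), hypoxia (0.00511) and lysosome (0.0566) lists turned, as did H2-DMb1 (0.0671), Ftl1 (0.0298), Hexa (0.0566) and Vegfa (0.0334). The muscle list forms the covariate, so the loss of its own rise was fixed in advance. For ribosomal proteins the median shrank to -0.33 and the median SE rose from 0.0714 to 0.102, and which of these ended the calls was not tested. Camera with an estimated correlation called 0 lists and 0 cell type lists (2 lists unadjusted), and fry called 2 lists and 0 cell type lists.

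When each library was left out, changed genes ranged from 643 (without control library 1) to 1457 (without C26 library 1), higher genes from 247 to 708 and lower genes from 367 to 749. Ptprc ranged from -0.0966 to 0.0637 and Cd274 from -0.0286 to 0.131. Of 81 named genes past the threshold, 41 passed in all 8 of these fits and 40 were lost in at least 1. Of 120 named values, 117 kept direction and side of the threshold with RLE factors, 115 of 115 with the stricter filter, 105 with limma-voom, 118 with TMM factors without ribosomal protein genes, 86 with offsets and 46 with the muscle covariate.

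The replicate number as a block gave 1184 genes, 1002 of them shared, but libraries of the same number did not deviate together (correlations across genes of -0.0234, 0.135, -0.0195 and 0.0934). The setting for another unit was not run, since the table held counts. Genes near 1 CPM rest on few reads.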

Other observations

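The lists of 5' TOP and imprinted genes were written after the main results were seen, and both tests left out the genes that prompted them. Other genes at the same loci as these were not sought or left out. Some genes outside the ribosomal protein list drew attention by their falls. Zfas1, a host gene of small nucleolar RNAs, had 434 CPM in control and 277 in C26 (log2 -0.65, edgeR adjusted p = 0.000186), and Snhg8, Snhg12 and the elongation factor gene Eef1b2 fell by 0.51, 0.46 and 0.41 on the log2 scale. So did Fau, which encodes a ribosomal protein fused to a ubiquitin-like protein, by 0.63, and Taf15, which is not a translation gene, by 0.50. The hypothesis was that transcripts with a 5' terminal oligopyrimidine tract (5' TOP), a class whose translation depends on growth signals, fell as a class. Of 29 tested others 16 fell, among them Gas5 (1020 to 799 CPM), Snhg6 (128 to 93.6 CPM), Rack1, itself part of the small ribosomal subunit (2450 to 1900 CPM), and Naca (953 to 760 CPM), while Eef1a1 (7510 against 6790 CPM) and Pabpc1 (1920 against 1840 CPM) did not pass. The median of the list was -0.265, below all of 10000 random lists matched on level, length and GC (95% of these lay between -0.17 and -0.05). Genes were drawn singly, so this rank measures the spread over genes and not over the libraries of each group. It also takes no account of list members that vary together, and so can overstate the evidence. A shared regulation of 5' TOP transcripts may include more than ribosomal protein genes, as a hypothesis found and tested on the same libraries.

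Several imprinted genes were higher in C26 tumours. Plagl1, a growth-restraining transcription factor gene, had 30 CPM in control and 48.8 in C26 (log2 0.70, edgeR adjusted p = 0.000437), and the noncoding Rian had 2.17 and 5.56 CPM (log2 1.35, edgeR adjusted p = 0.00214). Of 14 other tested imprinted genes 5 rose, namely Meg3 (3.61 to 7.56 CPM), Mest (3.7 to 8.58 CPM), Grb10 (3.93 to 6.38 CPM), Igf2r (66.1 to 83.2 CPM) and Airn (12.9 to 19 CPM), while H19 did not pass (127 against 147 CPM). Their median of 0.266 lay at percentile 99.5 of the matched random lists (95% of these lay between -0.05 and 0.23). This rank has the same limits as that of the 5' TOP list, and genes that share a locus were counted separately. The fibroblast and muscle lists moved in the same direction, and a larger share of stroma could account for this rise as well as a change in imprinted genes themselves.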
